A study of Mus musculus with 4 samples.

How the data were processed

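The study measured T cells of mixed bone-marrow chimeras with the 10x 5' version 2 assay for gene expression and for T cell receptor chains. Per the labels, marrow of Slc23a2fl/fl donors (control) or of Slc23a2fl/fl Cd4Cre donors (conditional knockout, cKO) was mixed with CD45.1 wild-type marrow. After 12 weeks, donor-derived CD45.2 single-positive TCRβ+ cells of spleen and lymph nodes were sorted. The 4 libraries are 1 gene expression library and 1 receptor library per genotype. The number of mice behind each library is not given in the sources used here.

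The deposited matrices hold UMI counts per gene and barcode, as whole numbers without normalization, for 32285 genes. Per the submitters' processing notes they were made with Cell Ranger 6.0.2 on genome build mm10. The gene annotation, the receptor reference and the barcode filtering settings are not given in the sources used here. The deposited receptor tables give reads and UMIs per contig as counts, the number of barcodes per clonotype as counts, and each clonotype's proportion as a fraction of the cells in clonotypes. Clonotypes were used as the authors' tables define them. Gene coordinates and transcript lengths came from GENCODE vM21 (GRCm38), matched on gene identifier, with 32158 of the 32285 identifiers found.

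Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrially encoded genes. This left 10289 of 10421 control barcodes and 9282 of 9427 cKO barcodes. Scrublet, run on each library with an expected rate of 8%, called 0 doublets in both, so it has not worked here. Barcodes with 2 or more productive TRB chains (646 control, 597 cKO) were left out as doublets, which removes only part of the doublets. The kept barcodes numbered 9643 and 8685. An alternative that also left out the 8% of cells with the highest Scrublet scores in each library was added after seeing the data.

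Both libraries were clustered together on log-normalized counts, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, without batch correction. Receptor, immunoglobulin, haemoglobin, mitochondrial, ribosomal and sex-linked genes and Slc23a2 were kept out of the variable genes. A cluster counted as T cells when at least 50% of its barcodes had a TRB chain. Its 10 leading genes, ranked by fold over all other cells after adding 5 CPM, were compared with fixed marker lists, and names carry the ending "-like". A cluster was CD8 when Cd8a and Cd8b1 together exceeded Cd4 by a ratio of 20, and CD4 when that ratio was below 1. At least 3 markers named the regulatory T-like, memory or effector CD8-like, interferon, dividing, recently activated and innate-like clusters, with NKT and gamma delta markers counted together for the last. CD4 clusters with at least 50 CPM of Cd44 and under 100 CPM of Foxp3 were called antigen-experienced CD4-like. CD4 clusters below both limits were called naive CD4-like, unless markers of a memory, effector, follicular or regulatory list outnumbered those of the naive CD4 list. Cells of a cluster whose median depth lay below 0.333 of the library median were called low RNA. These limits were set after seeing the data. CD8 clusters 1, 2 and 9, with high Ccr7, are reported by number, because cluster 2 also carried markers of another class.

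UMIs were summed over the cells of a class in each library and divided by the class total, as CPM. With 1 library per genotype no test, p-value or standard error exists, and the differences have no replicate check. Intervals are exact 95% intervals (Poisson for CPM, conditional binomial for ratios, Clopper-Pearson for shares) and cover counting error only. They treat each UMI or cell as an independent draw. UMIs of the same cell and cells of the same clonotype are not independent. For such counts the intervals are narrower than the error of drawing cells or clonotypes. In each class, genes with at least 20 CPM in 1 library and at least 100 UMIs over both were ranked by log2 ratio of CPM, cKO over control. The 12 highest and 12 lowest were named in naive CD4-like cells and in CD8 clusters 1, 2 and 9, and the 6 highest and 6 lowest in the other 3 classes. Also named were the 10 genes of largest mean log2 ratio among those at least 1.5 times apart in 1 direction in all 5 classes, and Slc23a2, Tet1, Tet2, Tet3, Foxp3, Cd5, Nr4a1, Cd44, Ly6c1 and Cd69. Receptor segment, immunoglobulin, haemoglobin and sex-linked genes were not ranked. A gene or marker that meets a rule but is missing from the text is not reported here. A value of 0 counts would be raised to a floor of 3 counts in a ratio.

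For each of 30 gene lists the median log2 ratio was taken over members with at least 5 CPM in 1 library. Its percentile among 10000 random lists, drawn from the 100 genes nearest in expression to each member, describes the pair of libraries and is no test. The lists are ascorbate and glucose transporters, TET and DNA methylation enzymes, other ascorbate-linked dioxygenases, T cell receptor early response, tonic self-reactivity, receptor complex and proximal signalling, anergy, inhibitory receptors, regulatory T core, naive and quiescence, memory and effector, cytotoxic, cytokines and chemokines, type 17, follicular helper, NKT and innate-like, type I interferon response, endogenous retrovirus restriction and nucleic acid sensing, cell cycle, apoptosis regulators, glycolysis and hypoxia-inducible factor targets, nuclear oxidative phosphorylation, mitochondrially encoded, antioxidant response, iron handling, ribosomal proteins, heat shock and handling stress, free RNA from other cells, sex-linked, and congenic or strain-variable genes. The kinds of cell to be compared, the lists, the size rule for named genes and the alternatives not described as added were fixed before the data were examined. The limits that name the clusters, and the pooling of CD8 clusters 1, 2 and 9 in place of a naive CD8-like class, were set afterwards.

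Shares of cells with a UMI were taken after thinning each cell to 3500 UMIs, which left out 908 control and 703 cKO T-like cells with fewer. Clonal expansion was the share of cells with paired TRA and TRB chains in clonotypes of at least 2 cells, also at an equal number of cells by analytic rarefaction. V segments were counted once per clonotype in cells with 1 TRB chain, and segments with at least 1% in 1 library were ranked. CDR3β hydrophobicity was the mean Kyte-Doolittle value at residues 6 and 7, counted from the first cysteine.

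Alternatives covered the mitochondrial limit (5%), doublet removal, resolution (0.6 and 1.5), thinning before clustering, classes from marker UMIs, the scaling, the weight of cells, the expression minimum (50 CPM) and the clonotype definition. Added after seeing the data were the scalings and the weight of cells for all lists but the early response list, clustering without 80 genes named as apart between the libraries, other poolings of clusters 2, 5 and 9, and leaving out cells with Cd8a or Cd8b1 UMIs from the antigen-experienced CD4-like class. The calculations of the naive CD4-like comparison were tried on simulated data with 5705 genes, 200 of them changed. The counts were Poisson draws around means shared by both libraries apart from the planted changes, without variation among cells, mice or libraries. They check the calculation only and say nothing about the error in real libraries. In these draws 94.9% of the intervals held the true ratio and 98.5% of genes changed 1.5-fold were recovered. All of the named genes, 24 of 24, were changed genes with the right sign. Of 200 lists of unchanged genes, 97.0% lay between percentiles 2.5 and 97.5. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.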

Results

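Slc23a2 encodes a transporter that carries ascorbate (vitamin C) into cells, and Cd4Cre deletes a floxed gene in developing αβ T cells. The libraries compare T cells that arose from Cre-negative (control) or Cre-positive (cKO) marrow beside wild-type competitor cells in the same kind of recipient. The question, per the series title, is how ascorbate and TET activity bear on the reactivity of naive T cells and on peripheral tolerance. The control expression library held 10421 barcodes with 64727301 UMIs (median 5739 UMIs and 2035 genes per barcode), and the cKO library 9427 barcodes with 70841846 UMIs (median 6647 UMIs and 2302 genes). UMIs and genes per barcode were thus more numerous in the cKO library. The receptor libraries held 9777 control and 8348 cKO cells, of which 8329 and 7226 had both a TRA and a TRB chain. With 1 library per genotype, no difference below has a replicate check, and cells of 1 library are not replicates.

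Slc23a2 UMIs were fewer in the cKO library. Over all kept T-like cells, Slc23a2 (ENSMUSG00000027340, chromosome 2, 132052496 to 132145108, minus strand) had 530 UMIs in the control library (9.19 CPM) and 287 in the cKO library (4.85 CPM), a log2 ratio of -0.92. The log2 ratio was -0.93 (95% interval -1.47 to -0.42) in naive CD4-like cells, -0.96 (-1.37 to -0.56) in CD8 clusters 1, 2 and 9, and -2.00 (-2.92 to -1.12) in antigen-experienced CD4-like cells. In memory or effector CD8-like and regulatory T-like cells, with 20 and 28 UMIs and with 29 and 21 UMIs, the intervals reached from -1.55 to 0.23 and from -1.44 to 0.30. The tags come from the 5' end of the transcript, and which exons were floxed is not given in the sources used here. Tags outside the deleted part check nothing about the deletion.

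The cKO library held larger shares of memory or effector CD8-like cells, antigen-experienced CD4-like cells and innate-like T cells. The share of regulatory T-like cells was nearly equal, and higher in the cKO library under some of the settings tried. Memory or effector CD8-like cells (cluster 6, 337 control and 641 cKO cells) made up 8.99% (8.09 to 9.95) of control CD8-like cells and 21.3% (19.8 to 22.8) of cKO CD8-like cells. Of all T-like cells they made up 3.53% and 7.84%. The size of this difference depended on the settings. The ratio of shares among CD8-like cells was 2.37, 1.61 by marker UMIs in thinned cells and 3.60 without doublet removal. Antigen-experienced CD4-like cells (cluster 3, 396 and 852 cells) rested on 2 markers of their class among the leading genes, and made up 7.64% (6.93 to 8.39) and 21% (19.7 to 22.2) of CD4-like cells. Naive CD4-like cells (clusters 0 and 8, 3188 and 1484 cells) accordingly made up 61.5% and 36.5% of CD4-like cells. This name rested mainly on the lack of other markers, with 1 naive CD4 marker among the leading genes of cluster 0 and 0 in cluster 8. Regulatory T-like cells (cluster 4, 628 and 520 cells) were 6.58% (6.09 to 7.10) and 6.36% (5.84 to 6.91) of T-like cells. Cluster 5, which carried both follicular helper and regulatory markers and was kept out of the regulatory class by a limit set after seeing the data, was 4.49% and 8.73%. CD8-like cells were 39.3% of control and 36.8% of cKO T-like cells. Innate-like T cells (clusters 14 and 16) were 1.06% and 3.67%. They were 0.134% and 1.08% when cells of high doublet score were left out. That setting removed most of the class and took the ratio from 3.47 to 8.12. Cells other than T cells, despite the sort for TCRβ, were 1.03% of kept control and 5.83% of kept cKO cells. Whether the purity of the sort bears on the innate-like share was not tested. Dividing cluster 17 held 0.367% and 1.53%, but 77.5% of its barcodes had a TRB chain and its leading genes included Mpo, Prtn3 and Elane, which belong to myeloid progenitors, so that its share is not one of T cells alone. Low-RNA cluster 13 held 1.05% and 3.8%, unnamed CD4 cluster 12 held 2.76% and 2.73%, and recently activated cluster 7 held 3.91% and 4.49%. Clusters with interferon-response genes made up 6.27% and 11.1% of CD8-like cells and 5.44% and 6.67% of CD4-like cells.

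**Figure D1:**
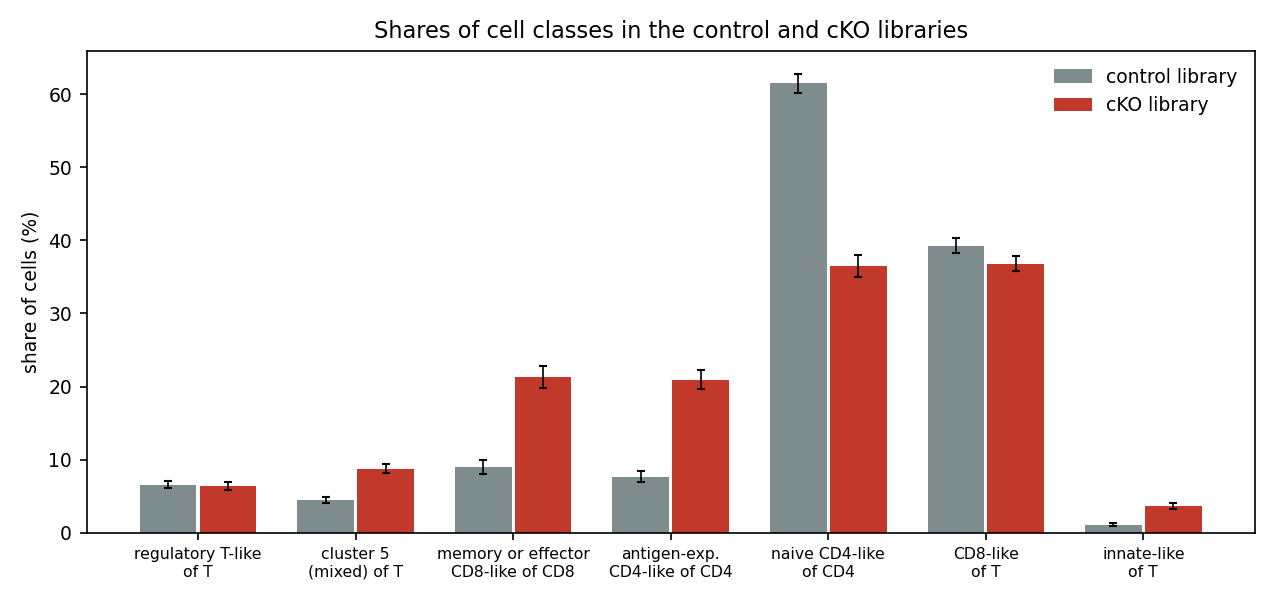
Share of cells (%) of 7 classes in the control and cKO libraries, with exact 95% intervals for counting error and 1 library per genotype. Memory or effector CD8-like cells stood at 8.99% and 21.3% of CD8-like cells, while regulatory T-like cells stood at 6.58% and 6.36% of T-like cells.

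CD8 cells with high Ccr7 lay in other clusters in each library. Cluster 1 held 65.2% of control and 15% of cKO CD8-like cells, cluster 2 held 8.91% and 46.2%, and cluster 9 held 10.6% and 6.47%. Cluster 2, with 334 control and 1392 cKO cells, may be a mark of the cKO library rather than a cell type. Its cells were therefore pooled with clusters 1 and 9 for the gene comparison. When the 80 genes that set the libraries apart were kept out of the clustering, memory or effector CD8-like cells were 14.6% of control and 31.5% of cKO CD8-like cells, and regulatory T-like cells were 8.93% and 10.1% of T-like cells. Classes taken from marker UMIs in cells thinned to 3500 UMIs gave 34.0% and 54.8% of CD8 cells with Ccl5, Cxcr3 or Il2rb (47.6% and 71.6% without thinning), 4.78% and 14.3% of CD4 cells with S100a4 (5.02% and 14.1%), and 6.38% and 8.64% of T cells with Foxp3 (8.39% and 10.8%). Foxp3 UMIs were present in 69.3% of control and 77.2% of cKO regulatory T-like cells after thinning (78.1% and 87.1% without; median depth before thinning 5199.5 and 6356 UMIs). The background share for Foxp3 in CD8 clusters 1, 2 and 9 was 0.519% and 0.945% (median depth 6673.5 and 7565 UMIs). For Ccl5, memory or effector CD8-like cells stood at 91.3% and 88.1% (median depth 8423.5 and 9620 UMIs), with a background in naive CD4-like cells of 1.36% and 4.29% (5237 and 5875 UMIs). For S100a4, antigen-experienced CD4-like cells stood at 25.2% and 29.4% after thinning, with a background in naive CD4-like cells of 0.104% and 0.501%. No background was taken for Cxcr3 or Il2rb.

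Naive CD4-like cells were compared between 1 library of each genotype, so their differences cannot be assigned to the deletion. The cKO library had more transcripts of Id2 and Ms4a4c, and far fewer of Gabrr2, Klhl5 and the heat shock genes Hspa1a and Hspa1b. Both heat shock genes belong to the list of heat shock and handling stress, and an effect of handling was not tested. Tet1 and Cd5, an inhibitor of receptor signalling whose level follows self-reactivity, were lower too. Cd5 lies close to Cd6 on chromosome 19, which was also lower, and Ms4a4c lies on that chromosome too. A donor difference in these regions was not tested. Lratd2 (ENSMUSG00000072568) had the highest log2 ratio, 2.73, from 4.87 CPM in the control to 32.4 CPM in the cKO library (81 and 280 UMIs). Ms4a4c had 1.997 (21.2 and 84.6 CPM), Rgs1 with 1.40, Pmepa1 with 1.26, Ide with 1.20 and Id2 with 1.15 (36.7 and 81.4 CPM). Pdxp (0.99), Pim2 (0.95), Stip1 (0.87) and Gm2000 (0.86) were higher too. Lgmn met the size rule but also defined the cells' own cluster and is not read as a difference. Gabrr2 (ENSMUSG00000023267) was lowest, with 385 UMIs in 341 control cells and 6 UMIs in 6 cKO cells, a log2 ratio of -5.06 (-6.51 to -3.92). Klhl5 (-3.15), Hspa1a (-2.80), Hspa1b (ENSMUSG00000090877, 2246 and 182 UMIs, -2.68), Usp18 (-1.86), Itga6 (-1.84), Ccnb1ip1 (-1.79), Gm19585 (-1.76), Ecm1 (-1.73), Dapl1 (-1.72) and Aim2 (-1.64) were lower as well, and Igsf23 was again a gene that defined a cluster. Of the genes fixed in advance, Tet1 had 196 and 36 UMIs (11.8 and 4.17 CPM, -1.50), Cd5 303 and 192 CPM (-0.66), while Tet2 (0.11), Tet3 (-0.19), Nr4a1 (0.08), Cd44 (0.01), Cd69 (-0.13) and Foxp3 (-0.31) lay closer together. Ly6c1 had a log2 ratio of -1.07 but is a gene that defined a cluster.

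**Figure D2:**
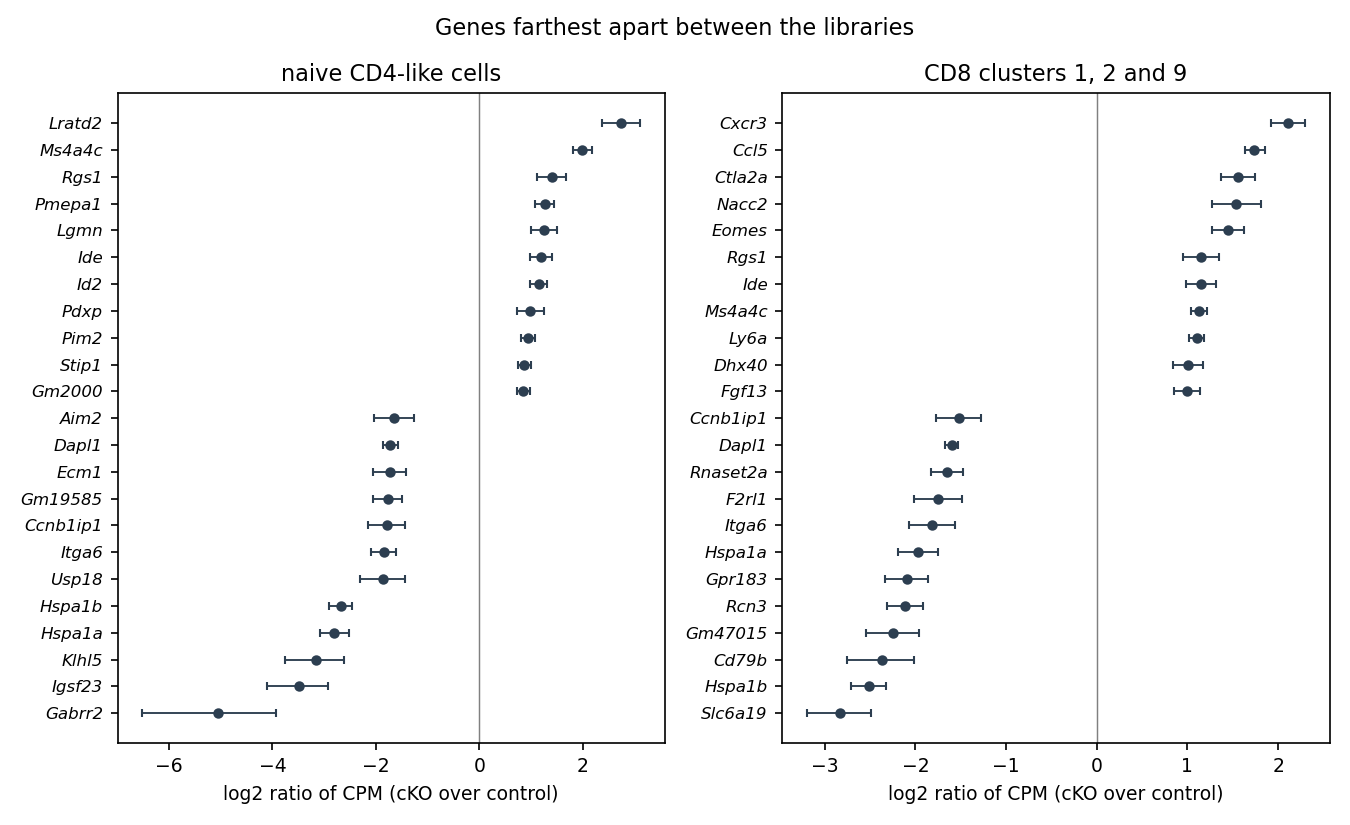
Log2 ratio of CPM (cKO over control) of genes among the 12 highest and 12 lowest in naive CD4-like cells and in CD8 clusters 1, 2 and 9, with exact 95% intervals for counting error. Gabrr2 lies lowest in naive CD4-like cells at -5.06, and Cxcr3 highest in the CD8 clusters at 2.11.

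Among gene lists in naive CD4-like cells, memory and effector genes, cytokines, cell cycle genes and glycolysis genes were higher in the cKO library. The lists of tonic self-reactivity, anergy and quiescence had lower medians. Memory and effector genes were higher for 9 of 14 members, with a median log2 ratio of 0.25 at percentile 99.9 of random lists. Vim (0.69) was among the higher members, and so was Ccl5 (1.33), whose background in these cells rose as given above. Whether free RNA, which was higher in the cKO library (median 3.87 for its list), raised this median was not tested. Crip1 (-0.73) and Itgb1 (-0.34) were among the lower members. Cytokine genes were higher for 5 of 6 members (median 0.24), with Ltb at 0.35 and Tgfb1 at 0.28. Glycolysis and hypoxia-inducible factor targets were higher for 16 of 20 (median 0.16), with Eno1 at 0.73, Gapdh at 0.43 and Pdk1 at -0.51, and cell cycle genes for 8 of 11 (median 0.21), with Mcm3 at 0.43 and Mcm2 at 0.42. The list of tonic self-reactivity was higher for 4 of 12 members, with a median of -0.19 at percentile 0.26. Nab2 stood at 0.21 and Cd6 at -0.94, and Cd5 is a member too. Ly6c1, set aside above as a gene that defined a cluster, is also among the lower members. The median of this list is not read as a measure of self-reactivity. Anergy genes were higher for 3 of 11 (median -0.12, percentile 1.94), with Cblb at -0.33 and Tox at 0.55. Naive and quiescence genes were higher for 7 of 18 (median -0.07, percentile 1.36), with Lef1 at -0.77, Satb1 at 0.26 and Igfbp4 at 0.56. The early response to the T cell receptor showed no common direction, with 7 of 15 members higher and a median of -0.01. Myc (0.48) and Nfkbid (0.43) were higher, and Cd40lg (-0.67) and Fos (-0.66) lower. TET and DNA methylation enzymes were higher for 3 of 8 (median -0.21, percentile 4.44), with Dnmt3a at 0.18 and Dnmt1 at 0.09.

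CD8 clusters 1, 2 and 9 (3177 control and 2038 cKO cells, median depth 6610 and 7551 UMIs) carried more transcripts of memory and effector genes in the cKO library. Cxcr3, Ccl5 and Eomes were among the 12 highest genes, and Cd5, Tet1, Itga6, Hspa1a and Hspa1b were lower, as in naive CD4-like cells. Cxcr3 (ENSMUSG00000050232) had 309 and 984 UMIs (14.2 and 61.1 CPM, log2 ratio 2.11). Ccl5 (1.74, 43.3 and 144.6 CPM), Ctla2a (1.56), Nacc2 (1.54), Eomes (1.45), Rgs1 (1.15), Ide (1.15), Ly6a (1.10) and Dhx40 (1.01) followed. Lower in the cKO library were Hspa1b (-2.51), Cd79b (-2.37), Gm47015 (-2.24), Gpr183 (-2.09), Hspa1a (-1.97), Itga6 (-1.81), F2rl1 (-1.75), Rnaset2a (-1.65) and Ccnb1ip1 (-1.52). Ms4a4c, Fgf13, Slc6a19, Rcn3 and Dapl1 met the size rule too but defined these clusters. Tet1 had a log2 ratio of -2.39 and Cd5 of -0.90, whereas Cd44 (1.35), Nr4a1 (0.72) and Ly6c1 (0.48) were higher. Tet2 (-0.29), Tet3 (-0.25) and Cd69 (-0.04) lay within a smaller distance. Foxp3 had a log2 ratio of 1.17 over these clusters, but of -0.10 in clusters 1 and 9 without cluster 2.

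Memory and effector genes in these CD8 clusters were higher for 14 of 19 members (median 0.47, percentile 100), with Il2rb at 0.48. All 7 cytokine genes were higher (median 0.58), among them Tnfsf8 (0.44) and Ltb (0.44). Cytotoxic genes were higher for 5 of 6 (median 0.33), with Nkg7 at 0.46, Prf1 at 0.23 and Klrd1 at -0.10. The type I interferon response was higher for 20 of 26 (median 0.23), with Slfn2 at 0.55 and Usp18 at -1.24. Early response genes were higher for 10 of 14, with a median of 0.05 that turned to -0.0186 under scaling by the median of ratios. Nfkbid (0.40) and Dusp2 (0.24) stood against Fos (-0.86) and Tagap (-0.26). Tonic self-reactivity genes had 6 of 13 members higher and a median of -0.10 (percentile 1.55), or -0.15 over the same 13 members when the total was taken without ribosomal, mitochondrial and receptor genes. That total lets 15 members pass 5 CPM, and their median was 0.42. Cxcr3, Eomes and Ly6a were higher members and Cd5 and Cd6 lower ones, so the median does not measure self-reactivity. Naive and quiescence genes (10 of 18 higher, median 0.01) had no fixed sign under the scalings tried. Satb1 was at 0.44 and Lef1 at -0.73. Ascorbate and glucose transporters were lower for all 4 members measured (median -0.42, percentile 1.78).

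In memory or effector CD8-like cells (median depth 8220 and 9543 UMIs) Gzma had the highest log2 ratio, 3.16, with 45 UMIs in 14 control cells and 898 UMIs in 43 cKO cells, and turned to -0.20 when cells of high doublet score were left out. Trdc (1.86, in 5 control and 43 cKO cells), Kcnc1 (1.70), Gm14085 (1.38) and Ccr2 (1.31) were also higher. Hspa1b (-2.66), Dapl1 (-2.52), Hspa1a (-2.39), As3mt (-2.24), Rcn3 (-2.24) and Als2cl (-2.18) were lower. Tet1 had 5 UMIs in the control and 2 in the cKO library (-2.48). Cd5 (-0.93) and Ly6c1 (-1.34) were lower, Nr4a1 (0.70) was higher, and Tet2 (-0.42), Tet3 (-0.19), Foxp3 (-0.62), Cd44 (0.07) and Cd69 (-0.29) are given for completeness. Memory and effector genes were higher for 14 of 24 members (median 0.14, percentile 93.7), with Lgals1 at 0.56 and S100a4 at -0.61. Tonic self-reactivity genes were higher for 5 of 16 (median -0.14), with Cd6 at -0.96. NKT and innate-like genes were higher for 3 of 9 (median -0.22, but 0.01 with the mean of each cell's CPM), with Plac8 at 0.56, Klra1 at -1.37 and Tbx21 at -0.38.

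Regulatory T-like cells bear on peripheral tolerance. Foxp3 stood at 543 CPM in the control and 612 CPM in the cKO library (log2 ratio 0.17), and the regulatory core list was higher for 11 of 19 members (median 0.06, percentile 74.5). Itgae (0.87) and Gpr83 (0.53) were higher and Ikzf4 (-0.75) and Ikzf2 (-0.58) lower. Penk (ENSMUSG00000045573) had 20 UMIs in 9 control cells and 378 UMIs in 43 cKO cells, a log2 ratio of 4.15. Penk is a leading gene of cluster 5, which was larger in the cKO library and where it stood at 62.6 and 1039 CPM. Hdac9 (1.63), Ms4a4c (1.58), Ifit3 (1.57) and Cd86 (1.49) were also higher, and Hspa1b (-3.59), Ifi208 (-2.96), Ccnb1ip1 (-2.77), Rln3 (-2.75), Gm19585 (-2.52) and Gpr183 (-2.18) lower. The type I interferon response was higher for 20 of 29 members (median 0.32, percentile 100), with Gbp2 at 1.36. Receptor complex genes were lower for most members, with 7 of 25 higher (median -0.12, percentile 0.17), and Cd3d at 0.36. Naive and quiescence genes were higher for 7 of 18 (median -0.16) and glycolysis genes for 15 of 21 (median 0.19), with Tpi1 at 0.67. Early response genes were higher for 10 of 19 (median 0.02), with Myc at 0.33, Fos at -1.17 and Cd40lg at -1.91. Tonic self-reactivity genes were higher for 5 of 13 (median -0.19), with Cd6 at -1.14. Tet1 (-2.16) and Cd5 (-0.84) were lower, as was Ly6c1 (-0.55), and Tet2 (0.21), Tet3 (-0.11), Nr4a1 (-0.19), Cd44 (0.17) and Cd69 (0.02) differed less.

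Antigen-experienced CD4-like cells of the cKO library carried more transcripts of receptors usual for cytotoxic cells. Klrd1 had 25 UMIs in 15 control cells and 486 UMIs in 153 cKO cells (log2 ratio 2.89), Cd160 20 UMIs in 11 cells and 369 in 107 (2.81), and Itgae 26 UMIs in 18 cells and 353 in 124 (2.37). Ctla2b followed with 2.11. Gzma, with the highest ratio (6.11, 2 and 362 UMIs), rested on 10 cKO cells, and 1 of them held 220 of the UMIs. Cells with UMIs of Cd8a or Cd8b1 were 12.4% (9.30 to 16) of control and 14.4% (12.1 to 17) of cKO cells of this class. As a background, Cd8b1 alone occurred in 11.4% of control and 5.65% of cKO naive CD4-like cells with at least 3500 UMIs. The cKO share thus stood farther above background, so these near-equal shares do not show an equal CD8 admixture. Without the cells with Cd8a or Cd8b1 UMIs, Klrd1 (3.08), Cd160 (3.16) and Itgae (2.74) stayed higher. An admixture of innate-like T cells, whose share was larger in the cKO library, was not tested. Cd160 is a leading gene of innate-like cluster 16. A430093F15Rik (-2.87), Eci1 (-2.63), Klhl5 (-2.54), Hspa1b (-2.50), Hspa1a (-2.34) and Dapl1 (-2.04) were lower, and 1700003C15Rik defined the cluster. Cd5 was lower by a log2 ratio of -1.77, Tet1 by -1.66 and Foxp3 by -0.89, while Nr4a1 was higher by 1.44 and Ly6c1 by 0.34. Tet2 (-0.25), Tet3 (0.02), Cd44 (-0.02) and Cd69 (-0.03) were close. Here the early response list was higher for 13 of 20 members (median 0.37, percentile 100), with Myc at 0.90, Nfkbid at 0.69 and Cd40lg at -0.72. Cytotoxic genes were higher for 10 of 12 (median 1.07), NKT and innate-like genes for 4 of 7 (median 1.59), cytokines for 8 of 10 (median 0.32), memory and effector genes for 16 of 24 (median 0.36) and glycolysis genes for 16 of 21 (median 0.31). Among the members of these lists, Ly6c2 (1.47), Ccl5 (0.92) and Egln3 (0.70) were higher, and Anxa2 (-1.56) and Gzmk (-1.83) lower. The type I interferon response was lower here, with 8 of 27 higher (median -0.15, percentile 0.52) and Slfn5 at -1.66. Tonic self-reactivity genes were higher for 4 of 14 (median -0.25) and anergy genes for 2 of 13 (median -0.12), with Cd6 at -1.97 in the former and Sirt1 at -0.49 in the latter.

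In all 5 classes, 31 genes were at least 1.5 times apart in the same direction, 6 higher and 25 lower in the cKO library. Among the 10 with the largest mean log2 ratio were Hspa1b (-2.79), Dapl1 (-2.00), Gpr183 (-1.66), Itga6 (-1.63), Rnaset2a (-1.53), mt-Atp8 (-1.44), Polr2l (-1.41), Eci1 (-1.23) and Cd6 (-1.18). Cd5 was among the 31 with a mean of -1.02, and so were the short ribosomal genes Rps29, Rpl38, Rps28, Rps27 and Rps21. The median log2 ratio of all genes with at least 20 CPM lay between -0.000531 and 0.07 in the 5 classes.

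**Figure D3:**
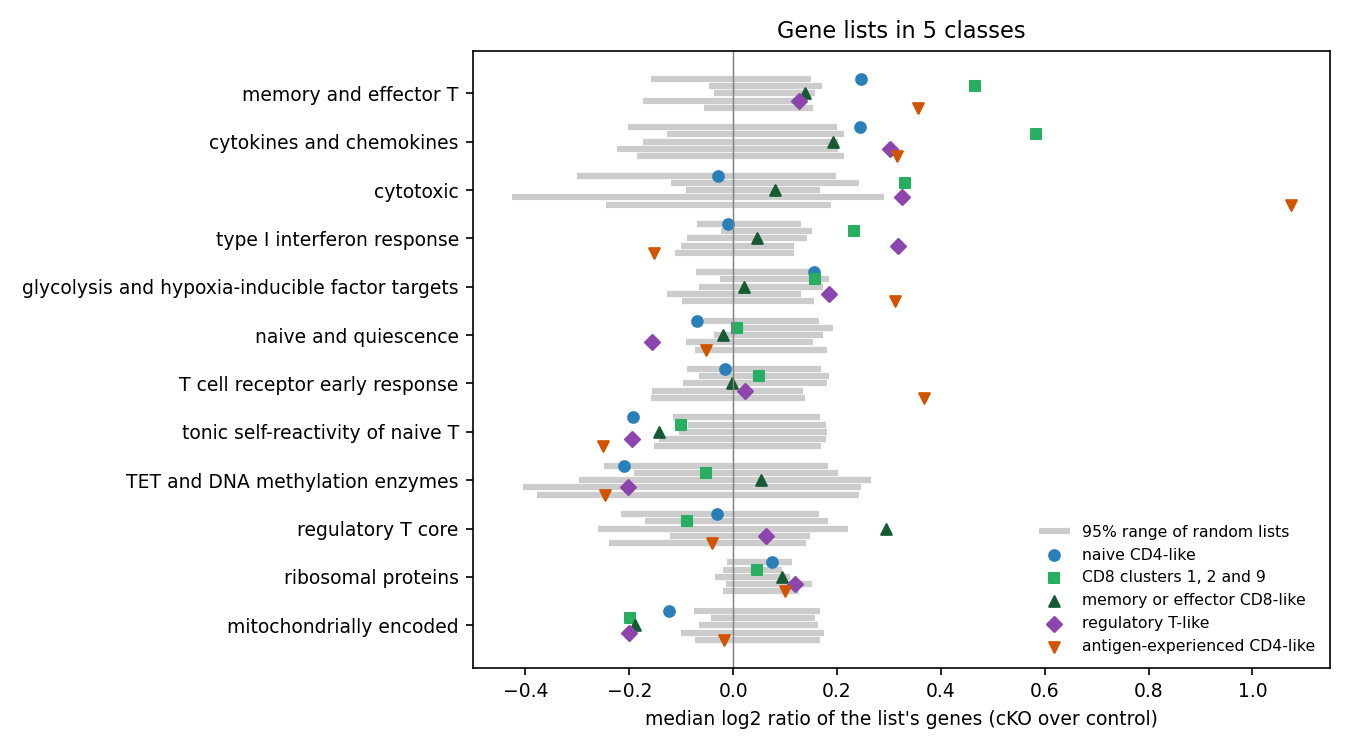
Median log2 ratio (cKO over control) of 12 gene lists in 5 classes, as coloured symbols, with the range of the middle 95% of random lists matched on expression as grey bars. Memory and effector genes lie at 0.25 in naive CD4-like cells and at 0.47 in CD8 clusters 1, 2 and 9, and tonic self-reactivity genes at -0.19 and -0.10.

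Among metabolic and housekeeping lists, mitochondrially encoded genes were lower in naive CD4-like cells and the CD8 clusters, with 4 of 13 higher in the former (median -0.12, percentile 0.3) and 3 of 13 in the latter (median -0.20), with mt-Nd3 at -0.59 and mt-Nd4 at 0.27 in naive CD4-like cells. In antigen-experienced CD4-like cells 6 of 13 were higher (median -0.02, percentile 10.6). Nuclear oxidative phosphorylation genes were higher for 18 of 30 in naive CD4-like cells (median 0.11) and for 24 of 30 in the CD8 clusters (median 0.16), although short members such as Atp5k (-0.89) and Cox7c (-0.57) were lower in naive CD4-like cells. Ribosomal protein genes were higher for 20 of 29 in naive CD4-like cells (median 0.07), with Rps29 at -1.17 and Rps27 at -0.83. Yet the median share of ribosomal protein UMIs per kept cell was lower in the cKO library, 31.1% against 34.9% in the control. In the CD8 clusters their median of 0.05 turned to -0.0216 and -0.00569 under other scalings. Antioxidant genes had 13 of 20 members higher (median 0.10) in naive CD4-like cells, with Gpx1 at 0.47 and Nfe2l2 at -0.27, and 12 of 20 in the CD8 clusters (median 0.07, -0.00259 under scaling by the median of ratios). In naive CD4-like cells, receptor complex genes were higher for 17 of 25 (median 0.09), ascorbate and glucose transporters for 0 of 3 (median -0.11, with Slc2a1 at -0.05) and inhibitory receptors for 1 of 4 (median -0.15, with Btla at -0.25). There, cytotoxic genes were higher for 3 of 7 (median -0.03, with Prf1 at -0.76), the regulatory core for 3 of 8 (median -0.03, with Icos at 0.38), type 17 genes for 2 of 2 (median 0.25, with Ramp1 at 0.09), NKT and innate-like genes for 1 of 2 (median -0.13), iron handling genes for 4 of 8 (median -0.02, with Ireb2 at -0.29) and heat shock and handling stress genes for 13 of 24 (median 0.05, with Hspa8 at 0.54). The list of congenic or strain-variable genes was higher for 3 of 10 (median -0.14, percentile 1.22), with H2-Q6 at -0.37. Some medians in naive CD4-like cells took either sign with the scaling or with the members that passed its limit of 5 CPM, namely other ascorbate-linked dioxygenases (13 of 22 higher, median 0.04, with P4ha1 at 0.22 and Kdm7a at -0.45), follicular helper genes (2 of 4, 0.11, with Sh2d1a at 0.29, through a 5th member), the type I interferon response (13 of 27, -0.01, with Ifi47 at 0.45), endogenous retrovirus restriction and nucleic acid sensing (4 of 8, 0.05, with Trim28 at 0.18, through a 9th member), apoptosis regulators (7 of 13, 0.04, with Bax at 0.38 and Fas at -0.29) and sex-linked genes (3 of 4, 0.02, with Ddx3y at 0.16). Free RNA from other cells was higher in the cKO library (3 of 4 members, median 3.87 in naive CD4-like cells and 3.0 in the CD8 clusters). UMIs of the neutrophil gene S100a8 occurred in 0.0348% of control and 4.44% of cKO naive CD4-like cells after thinning.

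Clonal expansion was greater in the cKO library and lay in the memory or effector CD8-like, antigen-experienced, mixed and innate-like clusters, not in the naive ones. Of T-like cells with paired chains, 3.14% (2.76 to 3.56, 239 of 7601) in the control and 13.4% (12.6 to 14.3, 870 of 6475) in the cKO library belonged to clonotypes of at least 2 cells. At an equal 6475 cells the control share was 2.8%, a ratio of 4.80. In cluster 5 the share was 22.3% and 66.2% (59.1% for cKO at an equal 364 cells), in antigen-experienced CD4-like cells 6.44% and 27.6% (18% at 326 cells), and in memory or effector CD8-like cells 0.758% and 12.6% (10.8% at 264 cells). In innate-like T cells it was 8% (6 of 75) and 24.9% (51 of 205), and 14.7% for cKO at an equal 75 cells. Within them, cluster 14 held 0 of 33 control cells (exact interval up to 10.6%) and 36 of 128 cKO cells (28.1%) in such clonotypes, and cluster 16 held 14.3% (6 of 42) and 19.5% (15 of 77, or 15.1% at an equal 42 cells). Naive CD4-like cells stood at 1.54% and 0.816% (0.723% for control at an equal 1225 cells), CD8 clusters 1, 2 and 9 at 1.36% and 1.11% (0.879% for control at 1615 cells), and regulatory T-like cells at 1.55% and 0.525%. The largest control clonotype had 10 cells, all in cluster 5. The largest cKO clonotype (TRBV17, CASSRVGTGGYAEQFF, with TRAV6N-7) had 29 cells, 21 of them memory or effector CD8-like, followed by clonotypes of 25 cells (TRBV26) and 23 cells (TRBV29) in cluster 5. Of the 10 largest cKO clonotypes, 8 lay mainly in cluster 5.

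**Figure D4:**
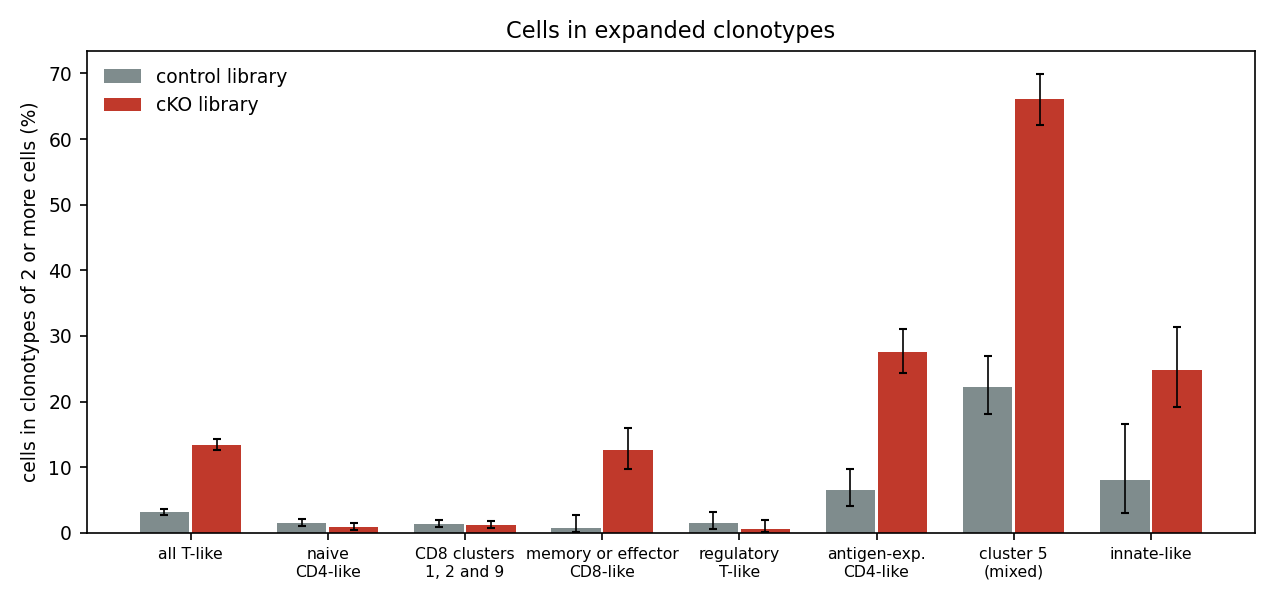
Share of cells with paired chains (%) that belong to clonotypes of 2 or more cells, by class and library, with exact 95% intervals for counting error. The share in cluster 5 was 22.3% in the control and 66.2% in the cKO library, and at most 1.54% in naive CD4-like cells.

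Receptor segments, counted once per clonotype, differed mainly among TRAV segments. Of 65 segments with at least 1% (20 TRB and 45 TRA), 35 had a higher and 30 a lower share in the cKO library. The highest ratio was that of TRAV11, the segment of invariant NKT receptors, with 0.496% and 1.5% (ratio 3.04), followed by TRAV13-4-DV7 (1.41), TRAV4-3 (1.37), TRAV21-DV12 (1.37) and TRAV6-7-DV9 (1.35). The lowest were TRAV9N-4, with 1.45% and 0.188% (0.130), TRAV14D-3-DV8 (0.388), TRAV6N-6 (0.467), TRAV5D-4 (0.474) and TRAV4D-4 (0.668). Within classes, TRAV9N-4 stayed low (0.157 in naive CD4-like cells and 0.155 in CD8 clusters 1, 2 and 9), but TRAV11 stood at 1.06 (2 and 1 clonotypes) and 0.515, TRAV4-3 at 1.09 and 0.902, TRAV21-DV12 at 2.28 and 1.03, and TRAV4D-4 at 0.605 and 1.12. Invariant NKT receptors (TRAV11 with TRAJ18) were carried by 25 of 7932 control cells (0.315%) and 83 of 6606 cKO cells (1.26%), a ratio of 3.99 (2.52 to 6.51). The CDR3β of naive CD4-like clonotypes had a mean length of 13.9 residues in both libraries. Their hydrophobicity at residues 6 and 7, a property linked with self-reactivity, was -1.22 in the control (SD 1.63) and -1.18 in the cKO library (SD 1.58). The values were -1.18 and -1.15 in CD8 clusters 1, 2 and 9 and -1.07 and -1.18 in regulatory T-like clonotypes. No paired nucleotide CDR3 occurred in both receptor libraries, and 63 TRB nucleotide CDR3 did.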

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

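The test of free RNA for the CD8 clusters was chosen after its result was seen, and the tests at high doublet score were added after seeing the data. With 1 library per genotype, a genotype difference and a difference between the libraries, the mice or the donors' strain background cannot be separated by any of these tests, and the strain of the donors was not tested.

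Genes with transcripts under 600 nt were lower in the cKO library in 4 of the 5 classes, with a gap to random lists matched on expression of -0.11 in naive CD4-like cells, but of -0.01, inside the range of random lists, in regulatory T-like cells. NK-like cluster 15, where Cd4Cre is not expected to act, had a gap of -0.14, which is consistent with poorer recovery of short cDNA in the cKO library. A lower content of ribosomal protein transcripts, with a median of 34.9% of UMIs per kept control cell and 31.1% per kept cKO cell, stays open as an explanation. Without ribosomal and mitochondrially encoded genes the gap in naive CD4-like cells was -0.0831, but the lower bound of -0.2 set for that test lay beyond the whole gap of -0.11, so the test could not have gone against this explanation and decides nothing. The median of these genes was -0.05, outside the range of random lists (-0.01 to 0.07). In regulatory T-like cells mt-Atp8 stood at -1.55, although short genes as a set showed no gap beyond random lists there. Whether ratios of very short genes such as Rps29, Rpl38 and mt-Atp8 come from recovery or from the cells stays open. They are therefore not read as biology here.

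Of the 31 genes apart in all 5 classes, 2 (6.45%) lie on chromosome 2 within 20 Mb of Slc23a2. This small share argues against DNA carried along with the targeted gene as a source common to all 31. Both donors are Slc23a2fl/fl per the labels, so DNA carried with the floxed gene could separate the libraries only where it differs between donors. Whether it does was not tested. The 2 genes, Mfap1a and Mfap1b, lie close together, and such a donor difference stays open for them. Dapl1, Itga6 and Rps21 lie on chromosome 2 outside that window, and a longer carried stretch was not tested. Poor recovery of short cDNA could account for part, since 10 of the 25 lower genes (40%) have transcripts under 600 nt, a share between the bounds set for either answer. Of the 6 higher genes, 2 (33.3%) had more CPM in cells other than T cells, which is too few to tell whether free RNA plays a part. Neither length nor the targeted locus applies to Cd5, Cd6 or Gpr183. For them an effect of the deletion and a difference in the donors' strain background both stay open and untested. Cd5 and Cd6 lie close together on chromosome 19. Stip1 and Ide, also on chromosome 19 and among the 31, were higher in the cKO library.

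Memory and effector genes were higher in CD8 clusters 1, 2 and 9 of the cKO library (median log2 ratio 0.47). Free RNA is argued against, since the list's median CPM difference was 0.936 in naive CD4-like cells and 15.9 in the CD8 clusters (5.88%). Doublets stay open. The median was 0.48 without cells of high Scrublet score, but this score found only 29.4% of control and 31.8% of cKO barcodes with 2 or more TRB chains, so the test decides nothing. Memory cells pooled into these clusters may explain a part, since at resolution 1.5 the median was 0.32, between the bounds set for either answer. An activated state of the cKO cells themselves stays open beside it.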

How the results depend on the processing

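The tests by high doublet score, by clustering without the genes apart, by other poolings of clusters, without cells with Cd8a or Cd8b1 UMIs, and by scaling or cell weight for lists other than the early response list, were added after seeing the data. The ratio of shares (cKO over control) for memory or effector CD8-like cells stayed above 1 under all alternatives, for antigen-experienced CD4-like cells it lay between 2.66 and 3.0 where the class existed, and for CD8-like cells between 0.888 and 0.959. No antigen-experienced CD4-like class formed without doublet removal or without the genes apart, so those alternatives gave no value. No paired analysis was possible because each genotype has 1 library.

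The regulatory T-like share was nearly equal or higher in the cKO library, depending on the settings. No setting tried gave a ratio with an interval wholly below 1. The main ratio of 0.966 (0.859 to 1.09) became 1.20 at 5% mitochondrial UMIs, 1.15 at resolution 1.5 and 1.13 without the genes apart. In these settings no mixed follicular and regulatory class formed, and a follicular helper class appeared. The regulatory T-like class then held 855 control and 860 cKO cells, 867 and 854, and 852 and 827, against 628 and 520. With cluster 5 counted as well the ratio was 1.36, which follows from the larger cluster 5 of the cKO library. It was 1.14 with thinned cells and 1.35 by marker UMIs, for which the cause was not tested. The intervals of all these higher ratios lay above 1, for counting error only. The memory or effector CD8-like ratio (2.37 of CD8-like cells) was 3.60 without doublet removal, 3.48 at resolution 1.5, 1.61 by marker UMIs and 3.77 with cluster 2, and as a share of T-like cells 3.33, 3.33 and 1.44 under the first 3 of these. The CD8-like ratio was 0.889 at resolution 0.6 and 0.888 with thinned cells. The causes were not tested.

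At a minimum of 50 CPM, which leaves fewer genes to rank, the number of genes named again was 10 of 24 in naive CD4-like cells, 10 of 24 in the CD8 clusters, 3 of 12 in memory or effector CD8-like cells and 5 of 12 in regulatory T-like cells. In the CD8 clusters 14 were named again with the total without ribosomal, mitochondrial and receptor genes (called the reduced total) and 15 in clusters 1 and 9 alone. In memory or effector CD8-like cells it was 5 without doublet removal and 6 at resolution 1.5, and in regulatory T-like cells 6 at resolution 1.5. Slc23a2 over all T-like cells was -0.69 with the mean of each cell's CPM. The early response list became -0.0186 in the CD8 clusters with the median of ratios and -0.14 in regulatory T-like cells without cells of high doublet score. The causes were not tested.

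Expanded cells were 4.28% and 14.7% by TRB chain alone, 0.881% and 9.20% with at least 3 cells (a stricter definition), and 4.47% of control cells over the whole receptor library. By amino acid, 3 paired and 431 TRB CDR3 were shared. Among values whose interval excluded 0, signs reversed for Foxp3 in the CD8 clusters (-0.10 in clusters 1 and 9), Gzma in memory or effector CD8-like cells (-0.20 without cells of high doublet score), follicular helper genes with the reduced total, which lets more members pass 5 CPM (-0.0251 in naive CD4-like cells with 5 members instead of 4, -0.0680 in the CD8 clusters with 5 instead of 3, but 0.08 and 0.37 over the same members), antioxidant genes in the CD8 clusters with the median of ratios (-0.00259) and ribosomal genes there (-0.0216 with the median of ratios, -0.00569 with the reduced total). For the others the causes were not tested. Of the other values, 762 for named genes and 381 for lists stayed within their intervals, and 74 and 40 moved. Some medians whose interval held 0 changed sign among these, such as tonic self-reactivity in the CD8 clusters (0.42 with the reduced total, through 2 more members) and NKT genes in memory or effector CD8-like cells (0.01 with the mean of each cell's CPM). Depth limits Slc23a2, Tet1, Foxp3 outside regulatory T-like cells and Nr4a1, whose counts per class were small.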

Other observations

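No tests were made for the values here, all of which were chosen after they were seen. Cells other than T cells were 99 of the kept control cells and 506 of the kept cKO cells, despite the sort for TCRβ. In cluster 16, 42.9% of control and 53.2% of cKO cells with a TRA chain had an invariant NKT receptor, and in cluster 14, 0 of 33 control and 22 of 129 cKO cells (17.1%) did.

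TRAV segments with D or N in the name, which belong to duplicated stretches of the locus, made up 47.6% of control and 40.4% of cKO clonotypes, and 13 of the 17 with at least 1% were lower in the cKO library, whereas 23 of the 28 other TRAV segments were higher. On chromosome 19, Cd5 (10717116 to 10739002), A430093F15Rik (10740947 to 10786043) and Cd6 (10789341 to 10830058) lie side by side and were lower in antigen-experienced CD4-like cells of the cKO library, and Ms4a4c (11404770 to 11427246) was higher in naive CD4-like cells.

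Xist had 79 UMIs in 16 of 641 memory or effector CD8-like cells of the cKO library, and 15 of the 16 had no UMI of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, against 24.5% of the other cells of that class. None of the 337 control cells of the class had an Xist UMI. In all other kept cells Xist had 8 UMIs in 3 of 9306 control cells and 17 UMIs in 7 of 8044 cKO cells.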
